A study of Drosophila melanogaster with 3 samples.

How the data were processed

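Droplet single-cell RNA sequencing measured transcripts in dissociated midguts of adult Drosophila melanogaster, pooled from 30 flies per sample, in 3 libraries with 1 library per group. Per the labels' protocols, tissue was dissociated with trypsin and elastase at 37 degrees, and libraries followed the standard 10x Genomics procedure. The deposited matrices hold raw UMI counts per gene and cell barcode, written by Cell Ranger 5.0.1 per the file headers. The genome build and gene annotation are not given in the sources used here. The 16727 features are gene symbols. Current names were taken from the gene table of the Release 6 plus ISO1 MT assembly, by which 12512 symbols were current, 3996 were synonyms, 119 were ambiguous and 100 had no match. No feature of the mitochondrial genome is present, so the planned filter on mitochondrial UMIs could not be applied. Groups came from the labels alone, from the genotype for control, the title for reprogrammed and the treatment for rescued. The labels give no replicate, batch or sex.

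Cells with at least 500 UMIs and 200 genes were kept, which removed 121 control, 151 reprogrammed and 333 rescued barcodes and left 64896417, 69974579 and 59840841 UMIs. Counts per cell were scaled to 10000, log-transformed and reduced to 2000 variable genes and 30 principal components, without integration of the libraries. A shared nearest-neighbour graph of 20 neighbours was divided by the Leiden method at resolution 1 with seed 1. A cluster was named when at least 3 markers of a list fixed in advance stood at least 2-fold above the other cells, unless its median was under 1000 UMIs, or its 10 leading genes held more markers of another class than of its own, or its median was under 1 in 3 of its libraries' median with no own marker among those genes. This naming rule was set after the data were seen, and the UMI minimum kept 1 cluster, cluster 11, out of the enterocyte-like class. Software was Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, scanpy 1.11.5, anndata 0.12.19, leidenalg 0.10.2, igraph 0.11.9 and matplotlib 3.10.9. Scrublet, as contained in scanpy, was run on each library and called 0 doublets in each, so it did not serve as a filter.

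UMIs were summed per library over all cells and over the progenitor-like, enteroendocrine-like and enterocyte-like classes. Levels are counts scaled to library size (CPM) divided by a median-of-ratios factor computed within each population, which for the whole libraries was 1.03 for control, 1.01 for reprogrammed and 0.959 for rescued. A gene was measured in a comparison when it had at least 100 UMIs over the 2 libraries. Ratios carry exact 95% binomial intervals, and a count of 0 was set to a floor of 3 UMIs per library to give a bound. Shares of cells carry exact 95% binomial intervals. With 1 library per group no test between groups and no p-value is given, and genes are counted by a size rule of at least 2-fold. Median ratios of gene lists with at least 4 measured members were placed among 10000 random lists matched on expression, and a list stood apart below percentile 2.5 or above 97.5. For shares of cells with a UMI of a gene, each cell was thinned to 2181 UMIs, the 25th percentile of the kept cells, and shallower cells were left out.

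Genes were named by a rule written before the data were examined, as were the cell filters, markers, gene lists, comparisons and the thresholds on ratios, UMIs of a gene and lists. For each comparison of whole libraries it takes the 5 highest and 5 lowest ratios among genes with a level of at least 50 CPM in the higher library. For reprogrammed against control and rescued against reprogrammed it takes the 3 highest and 3 lowest in each of the 3 classes. From a list that stands apart it takes up to 4 members, the 2 of highest level and the 2 of largest difference, and from other lists the 2 of highest level. InR, Sam-S, Gnmt, Sardh, E(z), Ldh, Thor, foxo, esg, Dl and pros are named in any case. With stg and CycE added, esg, Dl and pros were also fixed for the shares of cells with a UMI.

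Precision for counting error was tested on simulated data. UMIs of the same depth were drawn with 200 genes per comparison set to a known fold. Counts were drawn for summed libraries, with no spread between cells or between libraries. The simulation therefore gives no precision for genes whose UMIs lie in few cells. All genes set at 4-fold passed 2-fold, 41.8% to 59.7% of those set at 2-fold did, and all had the right direction. Of genes left unchanged, 2 passed 2-fold in enteroendocrine-like cells for reprogrammed against control and none in the other comparisons. Intervals held the set ratio for 94.8% to 96.3% of genes, for counting error alone. Alternatives fixed in advance were plain CPM, minimums of 30 and 300 UMIs, all deposited barcodes, a filter of 1000 UMIs and 500 genes, Leiden resolutions of 0.5 and 2, naming each cell by its marker score, thinning to equal UMIs, no thinning, and clusters weighted to the same mean shares. Added after the data were seen were the 3 epithelial classes alone, clusters within a class weighted alike, clusters of low UMIs counted with the class of their markers, the enterocyte-like class without cluster 14, and 3 removals of cells. These left out the 5% of cells of highest doublet score, cells of over 20000 UMIs, or, for each gene, the 10 cells with the most of its UMIs. Clusters were formed and named anew for all deposited barcodes, for the filter of 1000 UMIs and 500 genes and without the highest doublet scores. Counts of genes at least 2-fold different under the alternatives are given as a percent of measured genes, a form chosen after the results were seen because 3 counts could be printed only here. With at least 300 UMIs these were 205 genes over the whole library for reprogrammed against control, and, for rescued against control, 104 in progenitor-like and 104 in enterocyte-like cells.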

Results

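Single-cell RNA sequencing of dissociated adult midguts of Drosophila melanogaster was used to ask how the insulin signalling state of a mother's germline, and methionine in her diet, show in the gut of her offspring. The mothers of 2 of the 3 groups expressed a dominant-negative insulin receptor (InR-DN) in the female germline under the MTD-GAL4 driver, and all mothers were crossed to wild-type OregonR males. Control flies were progeny of mothers with the driver alone. Reprogrammed flies were progeny of InR-DN mothers, and rescued flies were progeny of InR-DN mothers that had been fed methionine, the precursor of the methyl donor S-adenosylmethionine. Each group had 1 droplet library made from a pool of 30 midguts, so no difference between the libraries has a replicate check and no test between groups was possible. The control library held 64973771 unique molecular identifiers (UMIs) in 6556 barcodes, the reprogrammed library 70067032 in 5936, and the rescued library 60049697 in 5933. After filtering, 6435, 5785 and 5600 cells were kept, in that order, with a median of 6277, 7036 and 6194.5 UMIs per cell. All intervals below are exact 95% intervals that cover counting error only, and ratios are given as log2 of the first-named library over the second.

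The cells formed 26 clusters, which were named from marker genes fixed in advance. Progenitor-like cells, which hold intestinal stem cells and enteroblasts, were the largest class in each library. They made up 59.3% of control cells (58.1 to 60.5%), 53.2% of reprogrammed cells (51.9 to 54.5%) and 55.6% of rescued cells (54.3 to 56.9%). Enterocyte-like cells, the absorptive and enzyme-secreting cells, made up 17.7%, 19.1% and 18.0%, and enteroendocrine-like cells, which secrete peptide hormones, 11.7%, 10.4% and 11.3%. Counted over these 3 epithelial classes alone, the progenitor-like share was 66.9% in control, 64.4% in reprogrammed and 65.5% in rescued, and the enterocyte-like share was 19.98%, 23.1% and 21.2%. The order of the progenitor-like shares depended on the setting. With the stricter filter, after which clusters were formed and named anew, they were 50.1%, 46.0% and 54.3%. Unnamed cells were then 23.1%, 23.0% and 17.3%, so the cells kept and the naming of clusters are not separated as the source of that order. The libraries also differed in cells of other tissues, and dissection is not separated here from dissociation or droplet recovery. Visceral muscle-like cells were 1.52%, 2.33% and 3.93% of the libraries, and Malpighian tubule-like cells 0.808%, 3.89% and 0.875%. Middle midgut-like cells, carrying genes of the copper and iron cell regions, were 4.48%, 4.96% and 3.13%, although the labels name the posterior midgut. Cells left without a name were 3.79%, 5.25% and 6.32%. Cluster 11, left unnamed for its low UMIs although it carries enterocyte markers, made up 1.10%, 2.47% and 5.13% of the libraries, and with it the enterocyte-like share would be 18.8%, 21.5% and 23.2%, so the order of these shares depends on it. Cluster 0 held the most progenitor-like cells in the control and reprogrammed libraries (1192 and 960), whereas clusters 0, 1 and 3 held 760, 753 and 753 in the rescued library. Cells of over 20000 UMIs held 67.2%, 74.4% and 71.7% of the UMIs of the enterocyte-like class, 36.0%, 50.9% and 39.1% of those of the progenitor-like class and 19.8%, 47.5% and 23.1% of those of the enteroendocrine-like class. In enterocyte-like cells they were 19.2%, 22.8% and 20.3% of the cells, so the sums of that class mostly describe these. Cluster 14, of 127, 175 and 131 cells with a median of 22258 UMIs, held 24.4%, 33.6% and 27.0% of the enterocyte-like UMIs, yet only 5 of 65 enterocyte markers were up in it and none led it, so its name is weak and values without it are given below.

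**Figure D1:**
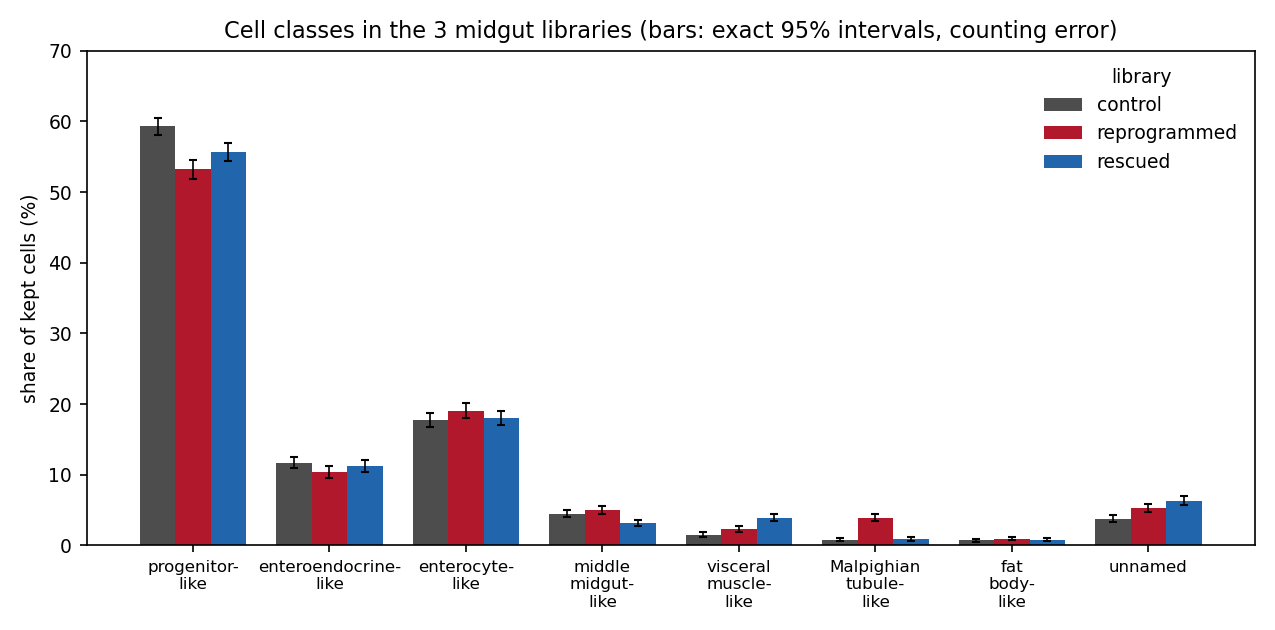
Share of kept cells (%) in each named class and in unnamed clusters for the control, reprogrammed and rescued libraries, with exact 95% binomial intervals for counting error. Progenitor-like cells were 59.3%, 53.2% and 55.6%, and Malpighian tubule-like cells were 3.89% of the reprogrammed library against 0.808% and 0.875% of the others. The fat body-like class, cluster 21, lost its name, with 0 markers up, when the 10 cells with the most UMIs of each gene were left out.

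The first comparison, reprogrammed against control, asked what maternal germline insulin receptor inhibition left in the adult gut of the progeny. In progenitor-like cells the reprogrammed library had higher Notch target, metallothionein and glycolysis transcripts, and lower transcripts of JAK-STAT and EGFR signalling and of immediate early and JNK genes. In enterocyte-like cells it had lower oxidative stress and detoxification and vacuolar ATPase transcripts, and in enteroendocrine-like cells lower peptide hormone transcripts. At least 2-fold differences were found for 96 of 6877 measured genes in progenitor-like cells (35 higher, 61 lower in the reprogrammed library), 48 of 4216 in enteroendocrine-like cells (12 higher, 36 lower) and 123 of 6262 in enterocyte-like cells (28 higher, 95 lower). Over the whole library the count was 340 of 8005 (196 higher, 144 lower), but with clusters weighted alike it was 219 (51 higher, 168 lower), and when only the 3 epithelial classes were summed it was 125 (45 higher, 80 lower), so the balance of higher and lower genes depends on the cells counted. In enteroendocrine-like cells the split was 13 higher and 14 lower without the highest doublet scores, with 12 of the 48 genes kept. Clusters were formed and named anew in that setting. The class then held 565 control and 424 reprogrammed cells, against 751 and 599 before, and 2458 genes were measured. Removal of doublets and naming of clusters are therefore not separated as the source of this change. Gene lists are placed by the percentile of their median among 10000 random lists of matched expression, as a description of these libraries. Random lists were drawn gene by gene, so a list whose genes vary together stands apart more easily. Over all populations and comparisons 247 list medians stood apart.

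In progenitor-like cells, 5 of 6 measured Notch targets were above 0, with a median log2 ratio of 0.40, higher than all 10000 random lists. E(spl)malpha-BFM, which responds to Notch in enteroblasts, had 9280 UMIs in control and 15877 in reprogrammed (0.79, 0.75 to 0.82), and the repressor gene E(spl)mgamma-HLH gave 0.74 (0.53 to 0.95). Several E(spl) genes were also among the markers that named this class. Cluster 1, led by E(spl) genes, held 673 of the 3816 progenitor-like cells in control and 765 of 3078 in reprogrammed, and with the clusters of the class weighted alike the median was 0.34. Of 15 genes of JAK-STAT and EGFR signalling, 14 were below 0, with a median of -0.28, lower than all random lists. Socs36E, a target and feedback inhibitor of JAK-STAT signalling, had 11311 and 5637 UMIs (-0.99, -1.04 to -0.95), the EGFR ligand gene vn 1439 and 461 (-1.63, -1.79 to -1.48), and the receptor gene Egfr gave -0.25. Immediate early and JNK genes had a median of -0.32 (10 measured, 7 below 0), lower than all random lists; with the stricter cell filter it was -0.17. Cluster 5 had upd2, upd3 and vn among its leading genes. It held 412 of the 3816 control and 239 of the 3078 reprogrammed cells of the class. Only 3 of 22 progenitor markers were up in it and none led it, so its name is weak. Values without it were not computed. With the clusters weighted alike the 2 medians were -0.26 (JAK-STAT and EGFR) and -0.26 (immediate early and JNK) and vn gave -1.23. Among the immediate early and JNK genes Mmp1, a matrix metalloproteinase gene, gave -1.07 and the stress gene Gadd45 -1.01, and kay, the Drosophila Fos gene, -0.36. The Notch ligand gene Dl, a stem cell marker, gave -0.31 (-0.35 to -0.27), while esg, which marks progenitors as a whole, had 12141 and 12032 UMIs and a ratio of -0.00 (-0.04 to 0.03).

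Metallothioneins and ferritins, which bind metal ions, had a median of 0.95 in progenitor-like cells (7 measured, 6 above 0), higher than all random lists. The metallothionein genes carried it: MtnE had 417 and 1325 UMIs (1.68, 1.52 to 1.84) and MtnC 47 and 158 (1.76, 1.28 to 2.26), whereas the abundant ferritin genes Fer1HCH and Fer2LCH gave 0.04 and 0.05. MtnC was also among the genes with the highest ratios in enterocyte-like cells, with 946 and 3439 UMIs (1.50, 1.39 to 1.60). It stood there at 72.5 and 204.6 CPM, against 1.09 and 3.70 in progenitor-like cells, where enterocyte markers were also higher (median 0.17), so free enterocyte RNA is not excluded as a source of the metallothionein UMIs of progenitor-like cells. Of 12 glycolysis genes, 11 were above 0 in progenitor-like cells, with a median of 0.22, higher than all random lists. Among these were Ald (0.22), Pgi (0.31) and Pglym78 (0.30), while Ldh, which turns pyruvate into lactate, gave 0.07 (-0.02 to 0.16). Ldh gave -0.80 (-0.89 to -0.72) in enterocyte-like cells and -0.70 (-0.81 to -0.59) in enteroendocrine-like cells. The highest single genes of the progenitor-like class were Mec2, with 1072 and 2989 UMIs (1.49, 1.39 to 1.59), Srg3, a gene regulated by STING, with 5675 and 15024 (1.42, 1.37 to 1.46), and the maltase gene Mal-A6 (1.13, 1.03 to 1.23). The lowest were CG14645, with 2576 and 2 UMIs (-10.32, -13.37 to -8.47), CG17145, a serine protease-like gene (-1.32), and Sirup, which encodes an assembly factor of respiratory complex II (-1.31, -1.40 to -1.21). CG14645, like CG34220 and CG34324 below, is among the leading genes of the unnamed cluster 24, and free RNA of the cells of that cluster is not excluded as the source of its UMIs in these classes. Srg3 is among the leading genes of cluster 14, and it was not tested whether free RNA of that cluster adds to its UMIs here; without cells of over 20000 UMIs its ratio was 1.04.

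Enterocyte-like cells of the reprogrammed library had lower transcripts for oxidative stress and detoxification, with 28 of 37 genes below 0 and a median of -0.48, lower than all random lists. GstD1, a glutathione transferase gene, gave -0.56 (-0.58 to -0.53), GstE3 -1.37 (-1.43 to -1.31) and the peroxiredoxin gene Prx2 -0.31; the list's median was -0.31 with the stricter cell filter and -0.33 without cluster 14. In progenitor-like cells the same list had a median of -0.11 (28 of 38 below 0, percentile 0.2), with GstD5 at -1.37. Genes of the vacuolar ATPase, the proton pump that acidifies endosomes and the gut lumen, had a median of -0.42 in enterocyte-like cells, and 18 of 19 were below 0. Vha16-1 gave -0.53 (-0.55 to -0.50) and Vha13 -0.45 (-0.48 to -0.43). The median of that list was -0.20 without cells of over 20000 UMIs, -0.23 with the class's clusters weighted alike and -0.33 without cluster 14. Jonah serine proteases, digestive enzymes of the class, had a median of 0.20 (13 of 15 above 0, percentile 99.96), with Jon99Fi at 1.03 (1.01 to 1.05). Carbohydrate digestion genes gave 0.27 (15 of 17 above 0) and heat shock genes -0.33 (6 of 10 below 0, with Hsp26 at -1.12 and Hsp83 at 0.21). Without cells of over 20000 UMIs these 2 medians were -0.01 and 0.17, neither apart from random lists. A difference in dissociation between the 2 libraries is also not excluded for the heat shock genes. Genes of JAK-STAT and EGFR signalling had a median of -0.19 in this class (10 of 12 below 0, percentile 1.48), with Socs36E at -0.69; without the cells of highest doublet scores it was -0.05, and without cluster 14 -0.19 at percentile 4.89. Among single genes, tobi, an alpha-glucosidase gene whose expression depends on brain insulin-like peptides, had 693 UMIs in control and 4 in reprogrammed (-7.80, -9.68 to -6.44), and 2 in rescued. The lipase-like gene CG6277 had 1907 and 50 UMIs (-5.62), with 90.7% of the control UMIs in 10 cells. CG34324 had 803 and 3 (-8.43, -10.71 to -6.88). The lectin gene lectin-37Da was highest, with 275 and 2029 UMIs (2.52, 2.33 to 2.70), followed by MtnC and hdly (1.23, 1.08 to 1.37). Without cells of over 20000 UMIs the ratio of hdly was 0.24.

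In enteroendocrine-like cells, 11 of 12 peptide hormone genes were lower in the reprogrammed library, with a median of -0.64, lower than all random lists. Orcokinin had 98899 and 72895 UMIs (-0.75, -0.76 to -0.73), AstC 36852 and 34137 (-0.42, -0.44 to -0.40), CCHa1 3461 and 2006 (-1.09, -1.17 to -1.01) and Mip 243 and 146 (-1.04). These peptides also served as markers of the class. The transcription factor gene pros, which marks the lineage, gave -0.58 (-0.70 to -0.46). Ribosomal protein genes had a median of 0.31 (83 of 84 above 0), higher than all random lists, with RpLP1 at 0.33 and RpS21 at 0.45. Without cells of over 20000 UMIs the 2 medians were -0.18 and 0.08. Erasp, a leading gene of clusters 14 and 23, had 69 and 266 UMIs (1.64, 1.25 to 2.04), or 0.77 without cells of over 20000 UMIs, and Mal-A6 78 and 238 (1.30, 0.93 to 1.69), or 0.77 without each library's 10 highest cells. CG18404 had 195 and 583 UMIs (1.27, 1.04 to 1.51), of which 86.1% of the reprogrammed ones lay in 10 cells, and gave -1.14 without each library's 10 highest cells and -0.73 without cells of over 20000 UMIs. The genes with the lowest ratios were CG14645 (435 and 1 UMIs, -9.07, -14.38 to -6.59), CG34220 (198 and 2, -6.94, -9.99 to -5.06) and CG34324, which had 397 and 0 UMIs and was at least 164-fold lower in the reprogrammed library.

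**Figure D2:**
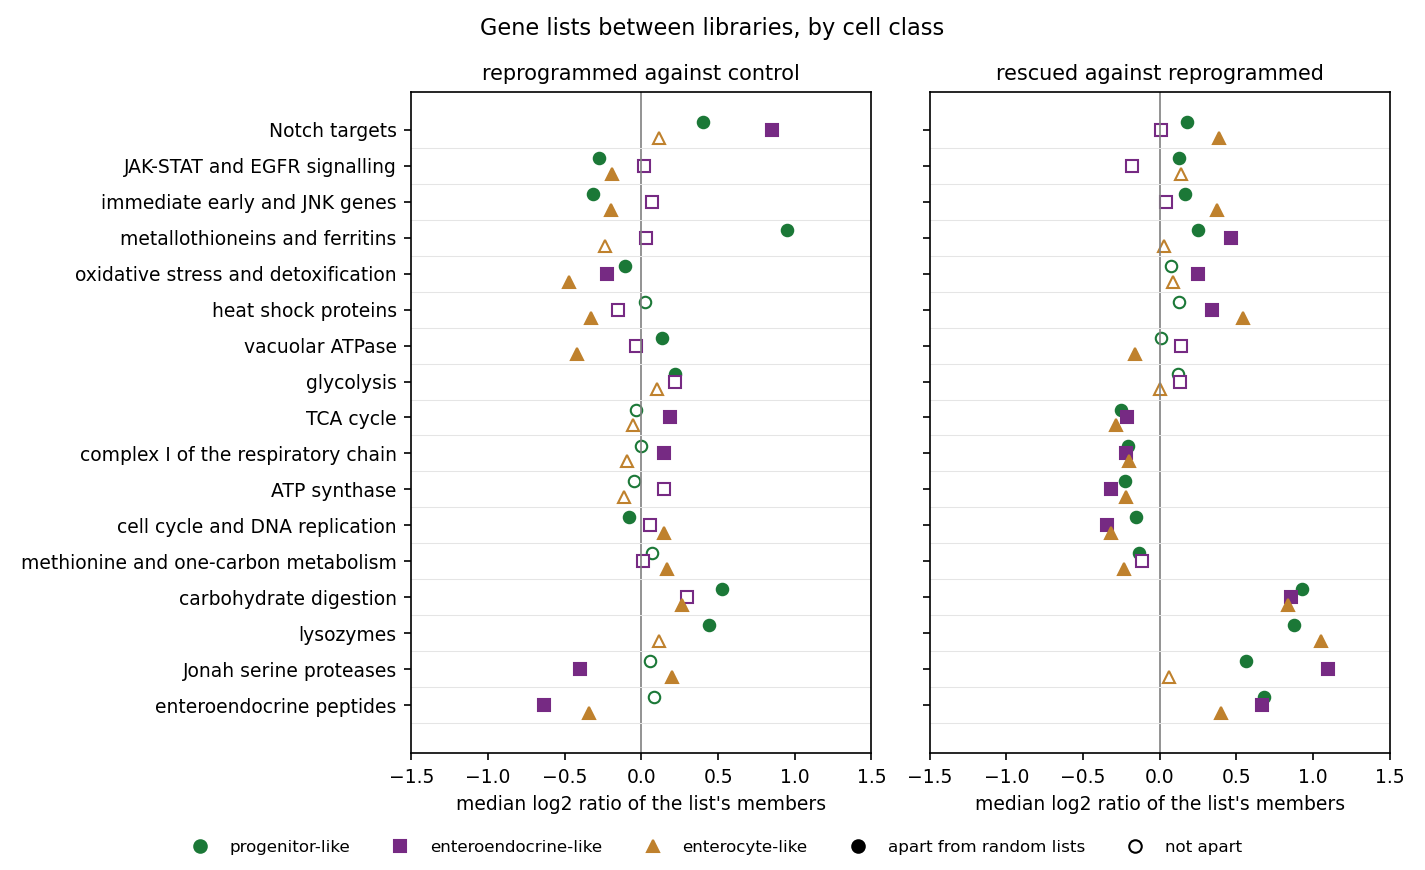
Median log2 ratio of gene lists for reprogrammed against control and rescued against reprogrammed, in progenitor-like, enteroendocrine-like and enterocyte-like cells; filled symbols mark medians outside the central 95% of 10000 random lists matched on expression. Notch targets stood at 0.40 in progenitor-like cells of the first comparison, and ATP synthase at -0.23, -0.32 and -0.22 in the 3 classes of the second.

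Genes of the pathways named by the design differed little at the level of the whole library. InR itself had a level of 89.0 CPM in control, 74.4 in reprogrammed and 81.0 in rescued, which does not check the labels because the transgene acted in the germline of the mothers. Reprogrammed against control, 23 genes of insulin and TOR signalling had a median of -0.03 (10 above and 13 below 0, percentile 16.0), with Thor, the 4E-BP gene, at -0.18 and foxo at 0.01 (-0.07 to 0.09), or -0.01 by plain CPM. The 28 histone methylation genes had a median of -0.05 (5 above and 23 below 0, percentile 9.86), with E(z), the methyltransferase of histone H3 lysine 27, at -0.05 (-0.18 to 0.09). For 16 genes of methionine and one-carbon metabolism the median was 0.12 (12 above 0, percentile 98.0), with Shmt at 0.25, Ahcy at 0.16, Sam-S, the S-adenosylmethionine synthetase gene, at 0.13 (0.08 to 0.17), and Gnmt at -0.52 (-0.78 to -0.26). With the 3 epithelial classes alone that median was 0.07, at percentile 89.6. Sardh had 0, 4 and 5 UMIs in the 3 libraries, too few for a ratio.

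The lowest ratios of the whole library came from few cells. CG34324, with 128228 UMIs in control, had 6 in reprogrammed (-14.47, -15.92 to -13.35), CG3906 had 53200 and 3 (-14.20, -16.48 to -12.66), CG43673 11384 and 1 (-13.56, -18.87 to -11.09), the mucin gene Muc68D 9755 and 2 (-12.34, -15.39 to -10.49), and Mco4, a multicopper oxidase gene, 4504 and 1 (-12.23, -17.53 to -9.75). Between 88.9% and 97.7% of the control UMIs of these 5 genes lay in 10 cells each. On the other side, CG6602 (51 and 3880 UMIs, 6.16, 5.76 to 6.59) had 92.3% of its reprogrammed UMIs in 10 cells and 3698 of them in the unnamed cluster 24, and the immune-induced gene IM33 (2.25, 2.16 to 2.35) 88.3%. Mur18B (3.52, 3.40 to 3.65), CG14245 (3.29, 3.18 to 3.40) and CG3168 (2.54, 2.46 to 2.61) were spread over more cells. Mur18B is among the leading genes of the Malpighian tubule-like cluster, and CG14245 and CG3168 of an unnamed cluster of 33 control, 89 reprogrammed and 12 rescued cells. Malpighian tubule genes had a median of 0.93 (8 measured, 5 above 0), with Uro, the urate oxidase gene, at 2.10 (1.90 to 2.31), and -0.51 with the 3 epithelial classes alone. Visceral muscle genes had a median of 0.80 (15 of 18 above 0, Mlc2 at 0.78) and -0.20 with the epithelial classes alone. No replicate stands behind these differences, and the mothers of the control flies lacked the InR-DN transgene, so inherited genotype and germline treatment are not separated.

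The second comparison, rescued against reprogrammed, held genotype constant and asked what feeding the mothers methionine did to the guts of their progeny. The rescued library had lower transcripts of respiratory complex I and ATP synthase in each of the 3 epithelial classes, lower TCA cycle transcripts in progenitor-like and enterocyte-like cells, lower cell cycle transcripts in progenitor-like cells, and higher transcripts of starch-digesting enzymes and lysozymes. Of 6853 measured genes, 102 differed at least 2-fold in progenitor-like cells (94 higher, 8 lower in the rescued library). The counts were 121 of 3978 in enteroendocrine-like cells (89 higher, 32 lower) and 124 of 6225 in enterocyte-like cells (102 higher, 22 lower), and 537 of 8058 over the whole library (424 higher, 113 lower). In enteroendocrine-like cells 32 of 2310 measured genes, 24 of them among the 121, passed without the highest doublet scores, where clusters were formed and named anew. Without cells of over 20000 UMIs 43 genes passed, 38 of them among the 121. By plain CPM (UMIs scaled to library size without the median-of-ratios factor), the split of the enterocyte-like class was 68 higher and 37 lower, since that scaling moved the median of all genes there to -0.14. Over the whole library, 353 genes passed 2-fold without cells of over 20000 UMIs (206 higher, 147 lower), among them 289 of the 537, and 125 with the 3 epithelial classes alone, among them 90 of the 537 in the same direction and 3 in the other.

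In progenitor-like cells all 31 measured genes of respiratory complex I were lower in the rescued library, with a median of -0.21, lower than all random lists. The other complexes did likewise: complex II had a median of -0.25 (4 of 4 below 0, percentile 0.8), complex III -0.26 (8 of 8, percentile 0.04), complex IV -0.25 (9 of 9, percentile 0.085) and ATP synthase -0.23 (11 of 11, percentile 0.22). ND-ACP, the mitochondrial acyl carrier subunit, had 21163 UMIs in reprogrammed and 14420 in rescued (-0.28, -0.31 to -0.25), COX5B 31707 and 21138 (-0.31, -0.34 to -0.29), SdhB 13276 and 9254 (-0.25, -0.29 to -0.21) and ATPsynbeta 69365 and 46504 (-0.30, -0.32 to -0.29). TCA cycle genes had a median of -0.25 (12 of 15 below 0, percentile 0.01), led by the citrate synthase gene kdn (-0.46, -0.54 to -0.39) and the pyruvate carboxylase gene PCB (-0.56, -0.73 to -0.39), while the malate dehydrogenase genes Mdh2 and Mdh1 gave -0.11 and 0.09. In enterocyte-like cells the medians were -0.20 for complex I (31 of 32 below 0, percentile 0.08), -0.37 for complex II, -0.28 for complex III, -0.22 for complex IV, -0.22 for ATP synthase (11 of 11) and -0.29 for the TCA cycle (13 of 15). Enteroendocrine-like cells gave -0.22 for complex I (31 of 31 below 0, percentile 0.11) and -0.32 for ATP synthase (11 of 11, percentile 0.01). These 2 medians were -0.13 and -0.20 without cells of over 20000 UMIs. Complexes II and IV had medians of -0.29 and -0.21 in this class, within the central 95% of random lists (percentiles 4.13 and 3.69). The complex I and ATP synthase medians stayed below the central 95% of random lists in all 3 classes under each of the 7 alternatives computed for list medians in every class.

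**Figure D3:**
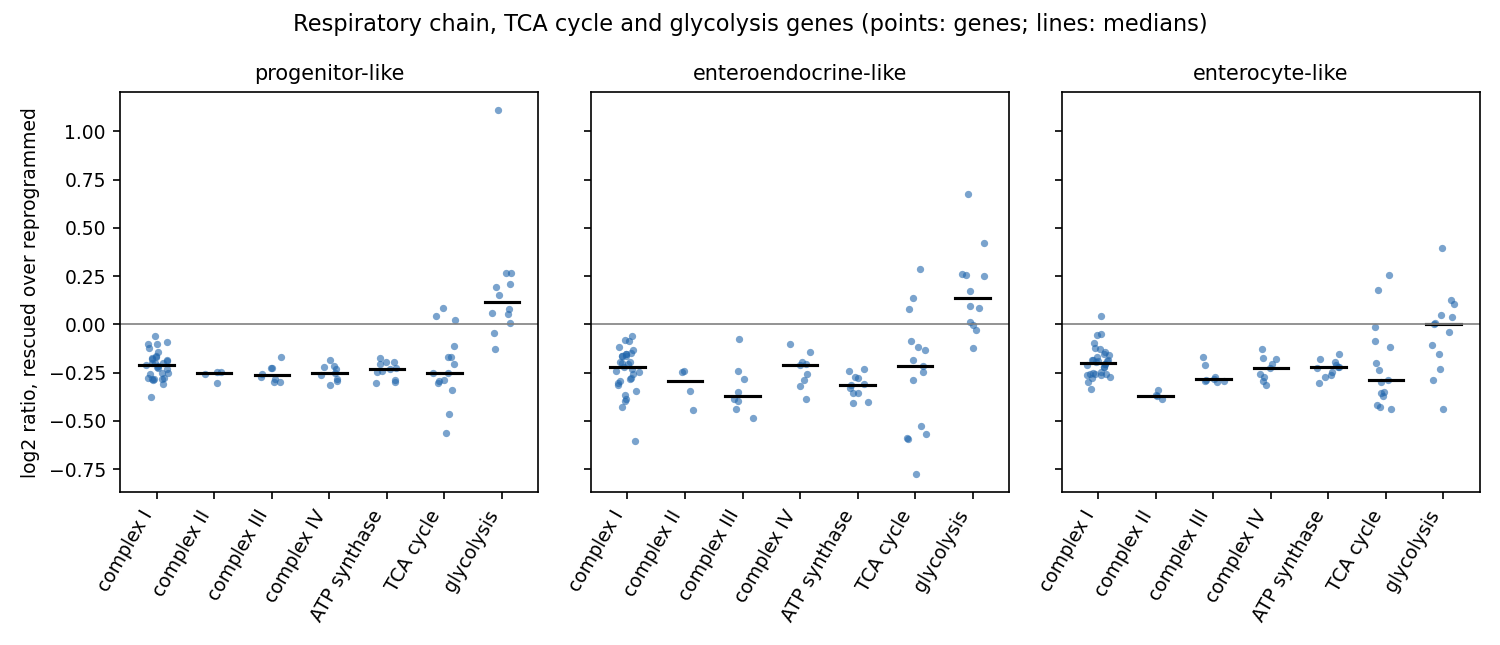
Log2 ratio, rescued over reprogrammed, of each measured gene of the respiratory complexes, ATP synthase, TCA cycle and glycolysis in the 3 epithelial classes; points are genes and lines are list medians. Complex I genes lay below 0 in 31 of 31, 31 of 31 and 31 of 32 cases in progenitor-like, enteroendocrine-like and enterocyte-like cells.

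Ldh stood against the respiratory genes in progenitor-like cells, where it had 2038 UMIs in reprogrammed and 3643 in rescued (1.11, 1.03 to 1.19). In enteroendocrine-like cells it gave 0.68 (0.56 to 0.80) and in enterocyte-like cells 0.05 (-0.05 to 0.15). Cell cycle and DNA replication genes had a median of -0.15 in progenitor-like cells (28 of 33 below 0, percentile 0.02), with PCNA at -0.27 (-0.33 to -0.21), CycE at -0.74 (-0.98 to -0.50) and the replication licensing gene dup at -0.52. The list's median was -0.08 with the clusters of the class weighted alike and -0.31 without cells of over 20000 UMIs. Cluster 2, with PCNA among its leading genes, held 585 of the 3078 reprogrammed and 345 of the 3116 rescued cells. Another makeup of clusters is therefore not excluded as a source of part of the median. In enterocyte-like cells the list gave -0.32 (21 of 25 below 0, lower than all random lists), with RnrL at -0.67, but -0.06 at percentile 28.2 with the stricter cell filter and -0.11 at percentile 17.4 without cluster 14, with 7 genes measured in each. Dl gave -0.15 (-0.20 to -0.10) and esg 0.18 (0.14 to 0.22) in progenitor-like cells. Srg3, which was high in the reprogrammed library, had 15024 UMIs there and 5290 in rescued (-1.23, -1.28 to -1.19), and Nazo, which like Srg3 responds to STING, had 4762 and 2250 (-0.81, -0.88 to -0.74). CG10208 was also among the 3 lowest, with 3046 and 1230 (-1.04, -1.13 to -0.94). Srg3 and Nazo are both among the leading genes of cluster 14, of 175 reprogrammed and 131 rescued cells. It was not tested whether free RNA of that cluster adds to their UMIs here. The 3 highest genes of the class, whe, CG16826 and lcs, are described with the whole library, because 10 cells held over 99% of their UMIs.

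Genes of starch and sugar digestion and lysozyme genes were higher in rescued enterocyte-like cells. Carbohydrate digestion genes had a median of 0.84 (15 of 16 above 0) and lysozymes of 1.05 (4 of 5 above 0), each higher than all random lists. The amylase genes Amy-p, with 14040 and 28404 UMIs, and Amy-d, with 13907 and 24139, gave 1.44 (1.42 to 1.47) and 1.22 (1.19 to 1.25), and the maltase genes Mal-A7 and Mal-A1 gave 1.48 and 0.56. LysD had 72876 and 112219 UMIs (1.05, 1.04 to 1.06), LysB 16775 and 33469 (1.42, 1.40 to 1.45) and LysC gave 1.10. Carbohydrate digestion was 0.54 with the clusters of the class weighted alike and 0.67 without cluster 14, and lysozymes were 0.64 without cells of over 20000 UMIs. Progenitor-like cells, which are not known to make these enzymes, showed the same direction at far lower levels, with medians of 0.93 for carbohydrate digestion (10 of 12 above 0, with Mal-A1 at 365 and 472 UMIs) and 0.88 for lysozymes (5 of 6, with LysD at 1214 and 1923), and free enterocyte RNA is not excluded as their source. In enteroendocrine-like cells the median was 0.86 for carbohydrate digestion (6 of 8) and 1.10 for Jonah proteases (13 of 13), whose median in enterocyte-like cells was 0.06 (8 of 15, percentile 33.5). The former was 0.45 at percentile 96.4 without each library's 10 highest cells of a gene. Heat shock genes had a median of 0.54 in enterocyte-like cells (8 of 10 above 0), with Hsp26 at 1.04 (0.96 to 1.13) and Hsp83 at -0.32, and 0.33 without cells of over 20000 UMIs. Immediate early and JNK genes gave 0.38 (7 of 9, with Jra, the Jun gene, at 0.40 and kay at 0.38), or 0.23 by plain CPM. For the heat shock and the immediate early and JNK genes, a difference in dissociation between the 2 libraries is not excluded. Cytochrome P450 genes gave 0.21 (34 of 42), or 0.06 by plain CPM and 0.11 at percentile 97.0 without cluster 14, with Cyp4e2 at 1.84 and the most abundant member, Cyp9b2, at -0.36, or 0.045 without each library's 10 highest cells of it. The 3 highest single genes were CG32284 (97 and 2314 UMIs, 32.1-fold, 92.4% of the rescued ones in 10 cells, or a log2 ratio of 2.90 without the 10 highest cells), the glutathione transferase gene GstD2 (3.03, or 0.98 without the 10 highest cells) and CG6283 (2.20, or 1.04). The lowest were CG17571, a serine protease-like gene (18620 and 6511 UMIs, -1.09, -1.13 to -1.05), lectin-37Da (-0.97) and the sterol-binding gene Npc2c (-0.94).

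Peptide hormone genes of enteroendocrine-like cells were higher in the rescued than in the reprogrammed library, with 11 of 12 above 0 and a median of 0.67, higher than all random lists. Orcokinin had 72895 and 113923 UMIs (1.30, 1.29 to 1.32), NPF 17837 and 23171 (1.04, 1.01 to 1.06), AstC gave 0.69, and Nplp2 had 267 and 1603 (3.24, 3.06 to 3.44). Without cells of over 20000 UMIs the median was 0.22. Cluster 18, led by NPF, held 70 of the 599 reprogrammed and 113 of the 631 rescued cells of the class, and cluster 9, led by Orcokinin, 151 and 197. With the clusters weighted alike the median was 0.57, and Orcokinin gave 0.86 and NPF 0.35. InR had 351 and 579 UMIs in this class (1.38, 1.19 to 1.58), at levels of 106 and 276 CPM, against 110 in control. Cpr51A, a cuticle protein gene (246 and 41 UMIs, -1.93), Srg3 (2156 and 479, -1.51) and CG10208 (-1.41) had the lowest ratios. For Srg3, free RNA of cluster 14 is not excluded here either. CG14645 (1 and 117 UMIs, 7.53, 5.02 to 12.84) and CG34324 (0 and 123, at least 64.7-fold) had the highest.

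Methionine and one-carbon metabolism genes were lower in the rescued than in the reprogrammed library, with a whole-library median of -0.17 (14 of 16 below 0, percentile 0.86). Sms, the spermine synthase gene, gave -0.50 (-0.58 to -0.42), Shmt -0.28, Ahcy -0.20 and Sam-S -0.24 (-0.29 to -0.19), while Gnmt, which consumes S-adenosylmethionine, gave 0.63 (0.37 to 0.89). In enterocyte-like cells the median was -0.24 (12 of 15 below 0, percentile 0.085), with Nmdmc at -0.59 and Sms at -0.57, but -0.09 at percentile 15.6 with the stricter cell filter and -0.13 at percentile 5.84 without cluster 14. Insulin and TOR signalling genes had a whole-library median of 0.12 (18 of 23 above 0, percentile 99.2), and 0.05 at percentile 90.5 with clusters weighted alike. By plain CPM the median of all genes in this comparison moved to -0.08, so the size of the list's median depends on the scaling. Thor gave 0.47 (0.45 to 0.49), foxo 0.25 (0.18 to 0.33), and Ilp3, an insulin-like peptide gene, 2.18 (960 and 3517 UMIs). Visceral muscle, where Ilp3 is known to be expressed in the gut, contributed 3.93% of rescued and 2.33% of reprogrammed cells. Histone methylation genes had a median of 0.03 (15 of 28 above 0, percentile 72.0), or -0.05 by plain CPM, with E(z) at -0.07 (-0.21 to 0.08).

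The highest whole-library ratios again came from few cells. CG16826 and lcs had 0 UMIs in the reprogrammed library and 69961 and 67769 in the rescued one, at least 28849-fold and 27946-fold higher. The gene whe had 2 and 60016 UMIs (15.18, 13.33 to 18.23). Of the rescued UMIs of these 3 genes, 97.7% to 98.8% lay in 10 cells each. CG34324 (14.36) and CG3906 (14.09) were back at 102225 and 42182 UMIs, with 95.7% and 96.1% in 10 cells. The genes with the lowest ratios were CG6602 (-4.64), the mucin gene Muc11A (12377 and 1162 UMIs, -3.11, -3.19 to -3.02), Scp2 (-2.35), CG14245 (-1.93) and CG3168 (-1.89), of which only CG6602 had most of its reprogrammed UMIs in 10 cells. The last 3 gave 0.02, 0.46 and 0.17 with clusters weighted alike. That setting gives each cluster the same share of cells in each library, but a cluster of deeper cells still adds more UMIs. Visceral muscle genes had a median of 1.36 (18 of 18 above 0, with Mlc2 at 1.49 and Mp20 at 1.74), and -0.56 with the epithelial classes alone. Malpighian tubule genes gave -0.26 (5 of 8 below 0, NaPi-T at -1.74) over the whole library, 0.41 with the epithelial classes alone and 0.32 with clusters weighted alike. The 2 libraries share a genotype, but with 1 library each the effect of methionine is not separated from that of the dissection, the dissociation or the droplet run.

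The third comparison, rescued against control, asked how far the rescued gut was from that of the control. At least 2-fold differences were counted for 187 of 6883 genes in progenitor-like cells (135 higher, 52 lower in the rescued library), 62 of 3711 in enteroendocrine-like cells (41 higher, 21 lower), 168 of 6067 in enterocyte-like cells (86 higher, 82 lower) and 533 of 8049 in the whole library (437 higher, 96 lower). With the 3 epithelial classes alone the last count was 203 (128 higher, 75 lower), among them 159 of the 533 in the same direction and 7 in the other. By plain CPM the medians of all genes moved to -0.11, -0.13, -0.12 and -0.10, in that order, and the splits in the 3 classes became 109 higher and 68 lower, 28 and 34, and 70 and 108. Metallothionein, Notch target and glycolysis genes stood above control in rescued progenitor-like cells, as they did in reprogrammed ones, whereas respiratory chain and cell cycle genes stood below. Both comparisons use the same control library, so a deviation of that library alone would give the same agreement.

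In progenitor-like cells metallothioneins and ferritins had a median of 1.01 (7 of 7 above 0, with MtnC at 2.06, MtnE at 1.48 and Fer1HCH at 0.34), higher than all random lists. Notch targets gave 0.39 (5 of 6, percentile 99.9), with E(spl)malpha-BFM at 1.03 (0.99 to 1.07). Glycolysis genes gave 0.31 (12 of 12, percentile 99.99), with Ldh at 1.18 (1.10 to 1.26) and Pgi at 0.57. Carbohydrate digestion genes gave 1.32 (11 of 11), at levels such as 8.87 and 13.3 CPM for Mal-A1 against 1602 and 2487 in enterocyte-like cells, so free enterocyte RNA is not excluded. On the lower side, complex I had a median of -0.19 (31 of 31 below 0, percentile 0.01), the TCA cycle -0.33 (12 of 15) and cell cycle genes -0.29 (28 of 33), the last 2 lower than all random lists. With the clusters of the class weighted alike the last 2 were -0.30 and -0.18, and cluster 2, with PCNA among its leading genes, held 744 of the 3816 control and 345 of the 3116 rescued cells of the class. PCNA gave -0.35 and Klp61F, a mitotic kinesin gene, -0.65. Dl gave -0.46 (-0.51 to -0.42), and Thor 0.46 (0.43 to 0.48). In enterocyte-like cells complex I gave -0.32 (32 of 32 below 0), vacuolar ATPase -0.59 (18 of 19) and oxidative stress and detoxification -0.36 (29 of 37), each lower than all random lists. Vha14-1 was at -0.83 (-0.86 to -0.79), Prx2 at -0.78 and GstD5 at -1.45. Carbohydrate digestion gave 1.05 (16 of 17, with Mal-A7 at 1.98) and lysozymes 1.22 (4 of 5, with LysB at 1.64), or 0.72 for lysozymes without cells of over 20000 UMIs. Over the whole library, insulin and TOR genes had a median of 0.08 (percentile 96.0), or -0.02 by plain CPM, histone methylation genes -0.08 (percentile 4.72) and methionine and one-carbon genes -0.06 (percentile 21.5). Visceral muscle genes gave 2.21 (17 of 18 above 0), with Hand at 2.95, and -0.50 with the epithelial classes alone, and Malpighian tubule genes gave 0.19 (percentile 93.5).

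The 5 genes highest in the rescued over the control library were CG16826, whe, lcs, CG45080 and CG34212, with 69961, 60016, 67769, 14455 and 5959 rescued UMIs against 0 in control for all but lcs, which had 7. The 4 with 0 were at least 27102-fold, 23249-fold, 5600-fold and 2308-fold higher, and lcs gave 13.46 (12.41 to 14.77). Mco4 (-3.03), CG43673 (-1.66), the lipase-like gene CG6277 (11995 and 3400 UMIs, -1.60), CG17145 (4710 and 1425, -1.51, -1.59 to -1.42) and CG17571 (19949 and 7262, -1.24) had the lowest ratios. Mco4 gave 1.00 with the epithelial classes alone. With genes set at least 2-fold above or at least 2-fold below both other libraries, 175 genes placed the control library apart, 214 the reprogrammed library and 347 the rescued library (329 of them above). With the 3 epithelial classes alone these counts were 72, 40 and 74. Genotype, diet and library all differ in this comparison.

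Shares of cells with a UMI of stem cell and division genes were compared after thinning each cell to 2181 UMIs, which kept 3470, 2819 and 2873 progenitor-like cells of the control, reprogrammed and rescued libraries and left out 346, 259 and 243. Their median depths before thinning were 8363.5, 10037 and 8770 UMIs. Enterocyte-like cells gave the background, except for CycE, which also acts in the endocycles of cells that become enterocytes. Their median depths were 3737.5, 4375 and 4231.5 UMIs, with 700, 690 and 604 cells thinned. A UMI of esg was found in 46.3%, 47.0% and 49.6% of progenitor-like cells, over a background of 11.6%, 8.84% and 12.3%, and the unthinned shares were 79.5%, 82.7% and 81.9%. For Dl the shares were 32.0% (30.4 to 33.5%), 31.0% (29.3 to 32.7%) and 26.2% (24.6 to 27.9%), over 11.1%, 8.12% and 8.77%, and 50.8%, 52.9% and 46.9% unthinned. The mitotic phosphatase gene stg was found in 8.27% (7.38 to 9.24%), 6.17% (5.31 to 7.12%) and 5.95% (5.11 to 6.88%), over 2.71%, 1.74% and 2.15%, and in 21.7%, 19.9% and 17.0% unthinned. CycE was found in 1.30% (0.947 to 1.73%), 2.16% (1.66 to 2.77%) and 0.975% (0.649 to 1.41%), and in 7.73%, 9.13% and 5.71% unthinned. It was found in 0.714%, 1.30% and 0.662% of enterocyte-like cells and in 0%, 1.63% and 0% of enteroendocrine-like cells, so the reprogrammed share was the highest in each class. In enteroendocrine-like cells, of which 319, 306 and 260 were thinned and 432, 293 and 371 left out, at median depths of 1854, 2234 and 1903 UMIs, pros was found in 53.6% (48.0 to 59.2%), 46.7% (41.0 to 52.5%) and 43.1% (37.0 to 49.3%). The background for pros was 1.00%, 1.01% and 0.993%, and the unthinned shares were 65.2%, 62.1% and 57.1%.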

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

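Of the tests in this part, those on how many cells held a gene set and those on the peptide hormone genes were chosen after the results were seen, and 3 were written before: the share of progenitor-like cells, the ratio of CG34324 to CG3906 and the markers of the source cells.

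Several gene lists stood on opposite sides of their random lists in 2 cell classes of the same comparison, and whether the classes differ was not tested. In reprogrammed against control, enterocyte markers were higher in progenitor-like (0.17) and enterocyte-like cells (0.08) and lower in enteroendocrine-like cells (-0.47), differences of 0.64 and 0.55. Jonah proteases were at 0.20 in enterocyte-like and -0.40 in enteroendocrine-like cells, a difference of 0.60. Vacuolar ATPase genes were at 0.13 in progenitor-like and -0.42 in enterocyte-like cells, a difference of 0.55, and at 0.11 and -0.59 in rescued against control, a difference of 0.70. Cell cycle genes were at 0.14 in enterocyte-like and -0.08 in progenitor-like cells of the first comparison, a difference of 0.22, but at -0.15 in enterocyte-like cells without cluster 14. In rescued against reprogrammed, ribosomal protein genes were at 0.07 in progenitor-like, 0.17 in enterocyte-like and -0.14 in enteroendocrine-like cells, differences of 0.22 and 0.32. By plain CPM the medians of all genes moved to -0.06, -0.14 and -0.08 in these classes, so the size of the first 2 values depends on the scaling. Visceral muscle genes were at 0.70 in progenitor-like cells (6 measured) and -1.34 in enterocyte-like cells (12 measured). The difference of 2.04 is thus between unlike sets of genes. Cells outside the comparisons also differed in number: visceral muscle-like cells were 2.33% of the reprogrammed and 3.93% of the rescued library and Malpighian tubule-like cells 3.89% of the reprogrammed library, each above the control's interval.

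A set of 27 genes, CG16826, lcs and whe among them, had 232709 UMIs in the rescued library and nearly none in the others. The 25 cells with the most of these UMIs held 98.3% of them. They lay in 8 clusters, and 9 of them were progenitor-like. That share cannot tell a few cells of another kind from rare cells of the classes. Expression across the progenitor-like class is argued against, because outside the 25 cells a UMI of the set was found in 8.59% of thinned progenitor-like cells (7.59 to 9.67%), 14.2% of enteroendocrine-like cells (10.2 to 19.1%) and 8.65% of enterocyte-like cells (6.53 to 11.2%). The unthinned shares were 25.4%, 25.04% and 29.9%. What these cells are, and whether methionine feeding of the mothers has a part in their presence, is not answered by 1 library.

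A second set of 16 genes, with CG34324 and CG3906, had 215367 UMIs in control, 183528 in rescued and 37 in reprogrammed. The 25 cells with the most, called source cells, held 95.2% of them in control and 96.7% in rescued, and only 2 reprogrammed cells reached the 25th percentile of the source cells' share of UMIs in 48 other marker genes (3 cells in a check added later, without 4 markers nearly missing there), as few cells collected in 2 of 3 dissections would give. Cluster 24, which holds 23 control and 15 rescued source cells, also has 17 reprogrammed cells, none of which reached that percentile with either choice of markers, against 6 or 7 control and 2 rescued cells of the cluster that were not source cells, but as CG6602 lies mostly in this cluster in reprogrammed (3698 of 3880 UMIs) and rescued (116 of 126; 24 of 51 in control), related cells with another programme in the reprogrammed library stay open. If the UMIs in the epithelial classes were free RNA of the source cells, CG34324 could be expected at the source cells' share of the sum of both genes, 70.4% in control and 70.8% in rescued, but only 1 of 6 class and library pairs had an interval that held it, the outcome named in advance for transcription in the classes, which however assumed 1 ratio for all source cells, and single ones with at least 1000 UMIs ranged from 0% to 90.1% in control and from 0% to 90.8% in rescued. Transcription in the classes and free RNA therefore cannot be told apart, and loss of the genes through the maternal germline stays open and untested.

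Peptide hormone genes were lower in enteroendocrine-like cells of the reprogrammed library, with a median of -0.64, and 47.5% of that class's UMIs lay in cells of over 20000 UMIs. Without those cells the median was -0.18, so mixed cells may account for most of the difference. They are argued against as the whole of it, because without cells of over 5000 UMIs the median was -0.21 at percentile 0.025, with 8 of 11 genes below 0. Other cell shares of the clusters alone are argued against as the whole of it too, with a median of -0.59 with clusters weighted alike. That setting kept the cells of over 20000 UMIs, and clusters of deeper cells still added more UMIs. Mixed cells and cluster makeup together were therefore not tested as the whole of the difference. A smaller peptide hormone difference that goes with germline InR-DN stays open as a hypothesis.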

How the results depend on the processing

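Of the settings below, the 3 epithelial classes alone, clusters within a class weighted alike, highest doublet scores, highest cells of a gene and cells of over 20000 UMIs left out and low-UMI clusters named by markers and cluster 14 left out of the enterocyte-like class were chosen after the data were seen, and the cause of a moved value was not tested except where fewer genes, UMIs or cells explain it by construction. No paired analysis was possible because each group has 1 library. Scrublet called no doublet and no mitochondrial feature exists, so 2 settings chosen in advance gave no value. Of 247 lists apart from random ones over all populations and comparisons, 245 stayed so on the same side by plain CPM, 226 with at least 30 UMIs, 200 with the stricter cell filter, 207 without the highest doublet scores, 214 without the highest cells of each gene and 192 without cells of over 20000 UMIs. Of 74 in the whole library, 56 stayed so with clusters weighted alike and 58 in the epithelial classes alone, and of 173 in the classes, 146 with clusters within the class weighted alike. Of 59 in enterocyte-like cells, 46 stayed so without cluster 14. Genes at least 2-fold different are given below as a percent of the genes measured, with the count before the bracket. For 3 values the count is in the processing summary only, because a number whose digits occur in a gene name of the design cannot be printed here, and the percent was chosen as the value for that reason after the results were seen. A value was called moved by the rule on counts, more than 1.5 times. The order is reprogrammed against control, rescued against reprogrammed, rescued against control. Over all measured genes of the report's setting they were 4.25%, 6.66% and 6.62% of the whole library, 1.396%, 1.49% and 2.72% in progenitor-like, 1.14%, 3.04% and 1.67% in enteroendocrine-like and 1.96%, 1.99% and 2.77% in enterocyte-like cells. With at least 30 UMIs, so that more genes of few UMIs were measured, they were 221 (2.93%), 215 (2.86%) and 348 (4.61%) in progenitor-like, 186 (2.87%), 309 (4.86%) and 243 (3.90%) in enteroendocrine-like and 217 (2.98%), 227 (3.12%) and 269 (3.74%) in enterocyte-like cells, and 564 (6.38%) and 830 (9.33%) for the first and last over the whole library. With at least 300 UMIs they were 2.85%, 346 (4.80%) and 347 (4.82%) over the whole library, 51 (0.829%), 60 (0.987%) and 1.71% in progenitor-like, 19 (0.990%), 40 (2.26%) and 22 (1.39%) in enteroendocrine-like and 72 (1.63%), 69 (1.57%) and 2.53% in enterocyte-like cells, and the genes that set a library apart were 111 for control, 131 for reprogrammed and 231 for rescued. With clusters weighted alike, the first 2 whole-library counts were 219 (2.74%) and 295 (3.66%), and 109 genes set control and 173 rescued apart. In the epithelial classes alone the counts were 125 (1.64%), 125 (1.65%) and 203 (2.67%), with 72, 40 and 74 genes setting the libraries apart. Without cells of over 20000 UMIs, rescued against reprogrammed gave 353 (4.64%) over the whole library, 43 (1.42%) in enteroendocrine-like and 75 (1.86%) in enterocyte-like cells, reprogrammed against control gave 17 (0.516%) in enteroendocrine-like cells, and 183 genes set rescued apart. Enteroendocrine-like cells, the shallowest of the 3 classes compared, gave 27 (1.098%) and 32 (1.39%) without the highest doublet scores, 24 (0.878%) and 48 (1.88%) at Leiden resolution 2, and 69 (2.58%) for rescued against reprogrammed with the stricter filter. Progenitor-like cells gave 61 (0.890%) for rescued against reprogrammed with clusters of the class weighted alike, and 123 genes set reprogrammed apart without the highest cells of each gene. Splits into higher and lower genes that turned or became even, for reprogrammed against control, were 51 and 168 over the whole library with clusters weighted alike, 45 and 80 in the epithelial classes alone, 43 and 43 in progenitor-like cells at Leiden resolution 2, and 13 and 14 in enteroendocrine-like cells without the highest doublet scores. In enterocyte-like cells the split of 28 and 95 became 55 and 75 with the stricter filter, 49 and 79 at resolution 0.5, 46 and 64 without cells of over 20000 UMIs and 52 and 79 without cluster 14. Shares of cells follow in the order control, reprogrammed, rescued. Progenitor-like cells were 54.1%, 46.5% and 52.9% at resolution 0.5, 56.2% and 53.6% (control and rescued) at resolution 2, 50.1%, 46.0% and 54.3% with the stricter filter, 52.3%, 51.4% and 52.3% without the highest doublet scores, 51.8% and 53.2% (reprogrammed and rescued) of all barcodes, 51.2% of reprogrammed cells without those of over 20000 UMIs, and 22.8%, 23.7% and 21.6% when each cell was named by its marker score. Enteroendocrine-like cells were 10.1%, 8.23% and 9.91% at resolution 2, 8.08%, 7.65% and 8.47% with the stricter filter, 9.18%, 7.65% and 9.24% without the highest doublet scores, 13.2%, 11.7% and 12.7% without cells of over 20000 UMIs and 6.50%, 5.15% and 6.39% by marker score. Enterocyte-like cells were 15.6%, 16.0% and 15.4% at resolution 0.5, 13.8%, 15.1% and 13.9% at resolution 2, 12.1%, 12.3% and 11.4% with the stricter filter, 16.5%, 18.0% and 16.6% without cells of over 20000 UMIs 12.7%, 13.6% and 15.8% by marker score and 18.8%, 21.5% and 23.2% with low-UMI clusters named by markers. Without thinning, a UMI was found in 79.5%, 82.7% and 81.9% of progenitor-like cells for esg, 50.8%, 52.9% and 46.9% for Dl, 21.7%, 19.9% and 17.0% for stg and 7.73%, 9.13% and 5.71% for CycE, and in 65.2%, 62.1% and 57.1% of enteroendocrine-like cells for pros. Reversed values were, without cells of over 20000 UMIs in reprogrammed against control, heat shock (0.17) and carbohydrate digestion (-0.0087) in enterocyte-like cells and CG18404 (-0.73, and -1.14 without its highest cells) in enteroendocrine-like cells. In the epithelial classes alone, where muscle and tubule cells are left out by construction, visceral muscle genes were -0.20, -0.56 and -0.50 in the 3 comparisons, Malpighian tubule genes -0.51 and 0.41 in the first 2, Mlc2 -0.61 and Mp20 -0.70 in rescued against reprogrammed, and Mco4 1.00 in rescued against control. With clusters weighted alike, Malpighian tubule genes were -0.37 and 0.32 in the first 2 comparisons, Uro -0.0435 in the first, and Scp2 0.023, CG14245 0.46, CG3168 0.17 and NaPi-T 0.13 in the second. Of the 3 classes compared, depth limits the enteroendocrine-like class most, with median UMIs of 1854, 2234 and 1903 per cell.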

Other observations

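The STING-responsive genes Takl1 and Sting were looked at only after Srg3 had been seen among the extremes, where the naming rule had also placed Nazo. The gene lists in this part were fixed in advance, and no explanation of the values was tested.

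Nazo had 3352 UMIs in control, 4762 in reprogrammed and 2250 in rescued progenitor-like cells, Sting 693, 910 and 707, and Takl1 61, 154 and 143. These counts are not scaled, and the class totals were 41750095, 42354972 and 36783478 UMIs. They therefore do not show that Sting and Takl1 had lower levels in rescued than in reprogrammed cells. Nazo and Takl1 are, like Srg3, among the leading genes of cluster 14, and free RNA of that cluster is not excluded as a source of their UMIs. Mitochondrial chaperone and protease genes were lower in the rescued than in the reprogrammed library, with medians of -0.18 in progenitor-like, -0.48 in enteroendocrine-like and -0.27 in enterocyte-like cells and 10 of 11 genes below 0 in each, among them Hsp60 at -0.25 in progenitor-like cells. With the stricter cell filter the progenitor-like median was -0.09, at percentile 5.68. Septate junction genes were higher in rescued progenitor-like cells (0.22, 11 of 12 above 0, percentile 99.9), with mesh at 0.74 and l(2)gl at 0.29, against reprogrammed. Circadian clock genes were lower in reprogrammed than in control progenitor-like cells (-0.16, 8 of 8 below 0, percentile 1.2), with vri at -0.31 and Pdp1 at -0.15. The yolk protein genes Yp1, Yp2 and Yp3, which adult female fat body expresses, had 3, 4 and 34 UMIs in control, 59, 54 and 69 in reprogrammed and 3843, 3853 and 11701 in rescued, and 10 cells each held 96.4%, 96.5% and 97.53% of the rescued ones. The labels give no sex.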
